A study of Mus musculus with 15 samples.

How the data were processed

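Whole lungs of wild-type CD1 mouse embryos (an outbred strain) were profiled by RNA sequencing in 15 libraries that the labels place in 5 groups of 3 replicates. Lungs taken on embryonic day 12.5 were kept for 48 h in culture at low or high transmural pressure, and other lungs were taken directly from embryos on days 12.5, 13.5 and 14.5. Per the labels' protocols, each RNA sample of the low pressure and E12.5 groups pooled 6 lungs and each sample of the other 3 groups pooled 3. The cultured and the freshly isolated lungs stand in separate tables of 6 and 9 libraries.

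Per the submitters' processing notes, reads were handled with cutadapt 1.6, Bowtie 1.1.1 and TopHat, counted with HTSeq and scaled with DESeq2, on genome build mm10. The gene annotation, the filters and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical gene copies, could not be assigned with certainty. 8 tables were deposited. The authors deposited raw read counts for 23420 genes in each of the 2 sample sets, and these whole-number counts were the input of every test. The deposited normalized tables hold a signal that is never negative: each count divided by 1 factor per library. For the time series these factors equalled median-of-ratios factors of its own 9 libraries, and for the cultured lungs those of all 15 libraries. The deposited log2 tables equal log2 of the normalized value plus 1, and further deposited log2 tables hold regularized values. No per-sample column was left out.

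Each raw table was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter by group, a robust quasi-likelihood fit and its F-test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. High was compared with low pressure, and the 3 stages were compared in pairs in a single fit. The difference between the E13.5 to E14.5 step and the E12.5 to E13.5 step was tested as a contrast of its own. Expression per library is given as CPM, raw counts scaled to the TMM effective library size as edgeR's cpm function does, and SD refers to the 3 libraries of a group. The SE of an edgeR log2 fold change was derived as its size divided by the square root of the F statistic. For genes with few counts it does not measure their precision. Adjusted p-values of single genes come from edgeR unless another tool is named, and those of gene lists from limma. The 38 gene lists (cell types, signalling pathways, matrix, cell cycle, stress and others) were written before the data were examined, as were the main tests and most alternatives. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and lists with fewer than 4 tested members were described by their members alone.

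The genes named in the text were set by a rule fixed in advance. For high against low pressure and for E14.5 against E12.5 it takes the 10 risen and 10 fallen genes with the largest fold change among those past the threshold, with a mean of at least 5 CPM, no overlap between the libraries of the groups compared and a symbol that is not a predicted or unnamed model. For each other time comparison it takes the first 4 each way. It adds up to 4 members of each list with the smallest p, 14 marker genes whatever their values, and the 6 genes with the largest smaller fold change in each direction among those called in both data sets. Because the planned time comparisons gave 0 genes, the rule was applied there to the fit with the replicate block. Members that moved against the direction of their list, and genes in counts of 5 or fewer, were named in addition, after their values were seen. Not every gene the rule takes is named in the text. Gene positions come from GENCODE mouse release M21 on the same genome build.

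Replicate numbers are shared by the groups of each table, so samples with the same number were checked for shared deviations from their group means. In the time series all 9 same-numbered pairs correlated at 0.397 to 0.838, against -0.736 to 0.625 for the 18 pairs with other numbers. The first principal component within groups held 74.2% of the variance and separated replicate 1 of every stage from replicates 2 and 3. Replicates 2 and 3 of different stages correlated with each other about as highly (up to 0.625) as their same-numbered pairs, so the shared structure is mainly that of replicate 1. The data thus set replicate 1 apart and do not pair replicates 2 and 3 by number, and the labels do not say what the numbers stand for. Fits with the replicate number as a block are given beside the planned fits, with a batch term for replicate 1 as a further setting. The cultured libraries showed no shared deviations by number. In none of the 15 pairs of libraries within a group did the counts agree within sampling noise.

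To relate pressure to stage, genes risen or fallen from E12.5 to E14.5 (adjusted p under 0.05 and an absolute log2 fold change of at least 1) were tested as sets in the cultured lungs with camera. The developmental score of a library is the mean log2 CPM of the risen set minus that of the fallen set, over the members tested in its own table. The planned sets were empty without the block, so sets from the blocked fit, an addition made after the data were seen, were used. Log2 fold changes of both data sets were also correlated across genes, with exact reassignment of the 6 pressure labels. For named genes with at most 3 counts in a compared group, a ratio with an exact 95% binomial interval, which covers counting error only, is given in place of a bound.

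Alternatives planned in advance were DESeq2 size factors, library totals alone, no filter or a minimum of 1 CPM, the replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, all 15 libraries in a single fit, a fold change minimum, and other definitions of the developmental sets. Added after seeing the data were a batch term for replicate 1, replicates 2 and 3 alone, offsets for GC content and transcript length fitted by splines with 5 degrees of freedom, removal from each library of the expression component along the replicate 1 difference of the time series (with limma-trend), and thinning of libraries to the shallowest. GC content and length were known for 98.8% of the genes tested in the cultured lungs and 98.9% in the time series. The offsets also set the mean log2 CPM of the libraries equal over these genes, so a shift shared by all genes goes with them.

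The tests were run first on simulated counts with real means and library sizes. For high against low pressure, edgeR recovered 67.7% of genes changed by a log2 fold change of 1 and 82.0% of those changed by 2, with 9 false calls among 14685 genes tested. On the same counts DESeq2 recovered 76.8% and 88% with 54 false calls, and limma-voom 67.7% and 82% with 5. For E14.5 against E12.5 the edgeR shares were 16.2% and 51.0% without the block and 79.8% and 94.9% with it, with 0 and 16 false calls among 14130 genes. These counts were simulated with a shift for each replicate number, which is the model of the blocked fit. The shares therefore do not test whether that block holds in the real libraries. With nothing changed, 0 of 37 lists were called, but the simulated genes varied independently of each other. This value therefore does not test list calls among correlated genes.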

Results

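The series addressed how transmural pressure, the pressure difference across the airway wall, bears on branching of the embryonic lung. Lungs explanted at E12.5 were cultured for 48 h at low or high pressure, and lungs isolated directly from embryos at stages E12.5 to E14.5 (days of gestation), with E13.5 between, gave the course of normal development, each group with 3 libraries of pooled lungs. The labels do not say whether the pools of a group came from separate litters or culture runs, so the p-values measure only the spread between these pools, which can be technical. Total counts per library were 31843739 to 38288861 at low pressure, 40167255 to 44341263 at high pressure and 18837343 to 21955244 in the time series. Low pressure and E12.5 libraries pooled 6 lungs each and the others 3, so pool size moved with pressure and with E12.5. The 80 ribosomal protein genes took 1.92% ± 0.140 of the counts at low and 2.97% ± 0.137 at high pressure (SD, n = 3). In the time series they took 3.32%, 3.73% and 4.05% in replicate 1 of the successive stages, and 1.66% to 2.09% in replicates 2 and 3. Low pressure replicate 3 had counts for 14637 genes, and the other 5 cultured libraries for 16509 to 16726.

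The first comparison asked which genes differed between lungs cultured at high and at low pressure. Genes of the alveolar epithelium and some of the conducting airways were higher at high pressure. Sftpc, which encodes surfactant protein C of the distal lung epithelium (chromosome 14, 70520949 to 70524081, minus strand), stood at 5.62 ± 3.22 CPM at low and 161 ± 43.4 CPM at high pressure (SD, n = 3), a log2 fold change of 4.86 (SE 0.40, adjusted p = 0.000398). Scgb3a2, a secretoglobin of the conducting airways (chromosome 18, 43764289 to 43767399, plus strand), rose from 1.24 ± 1.06 to 29.1 ± 16.4 CPM (SD, n = 3), with a log2 fold change of 4.58. The largest rise among genes with a mean of at least 5 CPM and no overlap between the groups was that of the club cell cytochrome Cyp2f2, at 6.19 (SE 0.80), from 0.149 ± 0.231 to 10.5 ± 3.56 CPM. Sftpb, which encodes surfactant protein B, rose by 2.82 on the log2 scale (SE 0.33). The other largest rises were those of Pitpnm3 (3.51), Spon2 (2.69), Igfbp7 (2.66), Cym (2.64), Steap4 (2.63) and the acute phase gene Saa3 (2.62), which has close paralogs.

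Among the genes that fell at high pressure were Hmga2 and Lin28b, members of the list of early embryonic timing genes, in which 3 of 11 members fell and 2 rose, also adjusted over the list alone, and which did not pass as a list (adjusted p = 0.443). Hmga2, which encodes a chromatin protein of early embryonic tissues (chromosome 10, 120361275 to 120476469, minus strand), went from 754 ± 47.5 CPM at low to 136 ± 13.1 CPM at high pressure (SD, n = 3), a log2 fold change of -2.47 (SE 0.11, adjusted p = 4.41e-05). Lin28b, an RNA-binding protein of developmental timing, went from 8.22 ± 1.93 to 2.90 ± 0.325 CPM (SD, n = 3; SE of the log2 fold change 0.24, adjusted p = 0.0036). Among the largest falls under the same rule were those of Irs4 (-3.91, SE 0.76), the potassium channel subunit Kcne3 (-3.09), the netrin receptor Unc5d (-3.04) and the collagen Col8a1 (-2.84). The transcription factors Sall1 (-2.77) and Hoxd3 (-2.74) and the membrane protein genes Tmem200a (-2.37) and Dpp6 (-2.36) fell too. Among the branching genes, Sox9, a transcription factor of the distal tips, fell by 0.81 on the log2 scale (SE 0.10, adjusted p = 0.00156), to 141 ± 11.7 CPM at high pressure (SD, n = 3), while Fgf10, the mesenchymal signal that draws out new buds, rose from 25.6 ± 3.41 to 42.3 ± 4.91 CPM (0.73). Bmp4 rose (0.41), Nkx2-1, the lung epithelial transcription factor, rose (1.06), and Myocd, an activator of smooth muscle genes, fell (-0.99). The fold changes of Sox2 (-0.13), Shh (-0.12), Acta2 (0.22) and Piezo1 (0.13) did not pass the threshold.

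**Figure D1:**
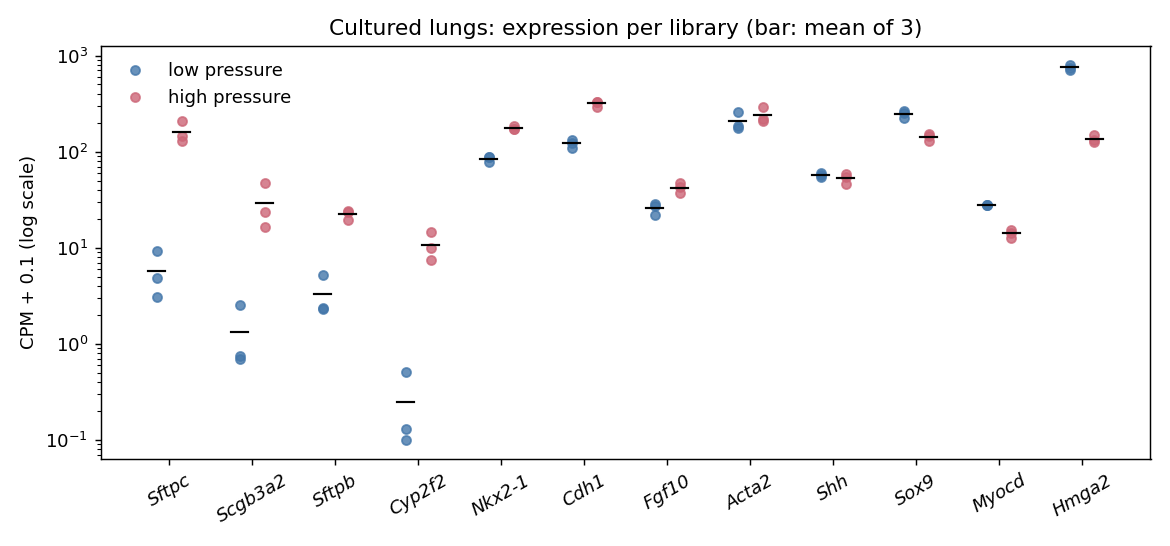
Expression of 12 named genes in each cultured library, in CPM plus 0.1 on a log scale. Points are libraries and bars are means of 3. Sftpc averaged 5.62 CPM at low and 161 CPM at high pressure, and Hmga2 754 and 136 CPM, without overlap between the groups, while the groups overlapped for Acta2.

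The pan-epithelial and alveolar lists were higher at high pressure, and the other epithelial lists did not pass. Of 17 pan-epithelial genes 16 rose, 0 fell and 1 did not pass, with 16 risen adjusted over the list alone, among them the adherens junction gene Cdh1 (1.38) and the keratins Krt19 (1.18) and Krt18 (1.09). The list passed (adjusted p = 1.57e-08), though with adjusted p = 0.556 with an estimated correlation. Of 17 alveolar type 1 and type 2 genes 12 rose, 0 fell and 5 did not pass, with 13 risen adjusted over the list alone. Examples were the tight junction gene Cldn18 (2.55), the mucin Muc1 (2.51) and the type 1 cell marker Ager (2.11). Here the adjusted p was 1.95e-06, and adjusted p = 0.466 with an estimated correlation. The distal tip list did not pass (adjusted p = 0.928): 4 of 12 members rose, among them Lamp3 (3.20) and Clu (1.79), and 3 fell, with 4 each way adjusted over the list alone. The proximal airway list did not pass either (adjusted p = 0.637): 5 of 10 members rose and the basal cell factor Trp63 fell, from 19.2 ± 5.86 to 4.78 ± 0.436 CPM (SD, n = 3), with the same 5 and 1 adjusted over the list alone. In the neuroendocrine list 0 of 8 members rose and 2 fell, also adjusted over the list alone (adjusted p = 0.637). In the channel list 7 of 15 members rose, among them the sodium channel subunit Scnn1g (1.68) and the sodium pump subunit Atp1b1 (1.32), and the mechanosensitive channel Piezo2 (-1.39) and the chloride transporter Clcn3 (-0.37) fell. Adjusted over the list alone 9 rose and 2 fell (adjusted p = 0.0291, and adjusted p = 0.556 with an estimated correlation). The share of ribosomal protein counts differed between the same libraries, at 2.97% at high and 1.92% at low pressure.

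The fibrillar matrix and basement membrane lists were higher at high pressure, though 10 and 7 of their members did not pass, and both calls ended when the component that separates replicate 1 of the time series was removed (adjusted p = 0.102 and 0.0552). Of 21 fibrillar matrix and elastic fibre genes 11 rose and 0 fell, or 12 and 1 adjusted over the list alone, with Eln (1.64), Col1a2 (0.96) and Sparc (0.88) as examples (adjusted p = 0.0204, and adjusted p = 0.781 with an estimated correlation). Of 16 basement membrane genes 8 rose, such as the laminin chain Lama5 (0.68), and Lama1, the chain of early embryonic laminin, fell (-1.16). Adjusted over the list alone 9 rose and 1 fell (adjusted p = 0.0204, and adjusted p = 0.680 with an estimated correlation). Among airway smooth muscle genes 4 rose, such as Des (0.84) and Mylk (0.55), 3 fell and 8 did not pass, with 4 each way adjusted over the list alone, and the list did not pass (adjusted p = 0.723). In the mitosis list 7 of 20 members rose, with Cdc20 (0.80) and Birc5 (0.62) as examples, and Bub1 fell (-0.53), giving 8 and 1 adjusted over the list alone (adjusted p = 0.0429, and adjusted p = 0.680 with an estimated correlation). In the list of cell cycle inhibitors and p53 targets 5 of 14 members rose and 0 fell, also adjusted over the list alone, among them Cdkn2b (2.49) and Cdkn1a (1.56), both inhibitors of cyclin-dependent kinases (adjusted p = 0.0374, and adjusted p = 0.680 with an estimated correlation). The interferon list had 6 of 13 members higher and 0 lower, also adjusted over the list alone, such as Ifit3 (1.75) and Irf7 (1.51), with adjusted p = 0.00948, and adjusted p = 0.741 with an estimated correlation.

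The hedgehog, Notch, endothelial, hypoxia and glycolysis, and cholesterol lists were lower at high pressure, though with an estimated correlation no list passed (0 of 37). Of 9 hedgehog pathway genes 6 fell and 0 rose, also adjusted over the list alone, among them the mesenchymal target Foxf1 (-1.24), Gli3 (-0.87) and the receptor Ptch1 (-0.84), with adjusted p = 0.00163, and adjusted p = 0.556 with an estimated correlation. Of 13 Notch pathway genes 4 fell, such as Hey1 (-1.18) and Jag1 (-0.92), and the ligand Jag2 rose (0.38). Adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.0233, and adjusted p = 0.680 with an estimated correlation). Endothelial markers fell in 3 of 15 cases, also adjusted over the list alone, namely Flt1 (-1.52), Cdh5 (-1.29) and Erg (-1.17), with adjusted p = 0.00948, and adjusted p = 0.781 with an estimated correlation. In the hypoxia and glycolysis list 9 of 18 members fell, among them Ndrg1 (-1.57), Bnip3 (-1.38) and the hexokinase Hk2 (-1.29), and the metallothionein Mt1 rose (0.87). Adjusted over the list alone 12 fell and 1 rose (adjusted p = 0.000944, and adjusted p = 0.719 with an estimated correlation). In the cholesterol and fatty acid synthesis list 7 of 18 members fell, such as Idi1 (-0.49) and Insig1 (-0.50), or 10 adjusted over the list alone, and 0 rose (adjusted p = 0.0113, and adjusted p = 0.794 with an estimated correlation). In the FGF list, which did not pass (adjusted p = 0.723), 4 of 14 members rose and 3 fell, among them Etv4 (-1.19) and Dusp6 (-1.08), targets of FGF signalling, with 4 each way adjusted over the list alone.

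**Figure D2:**
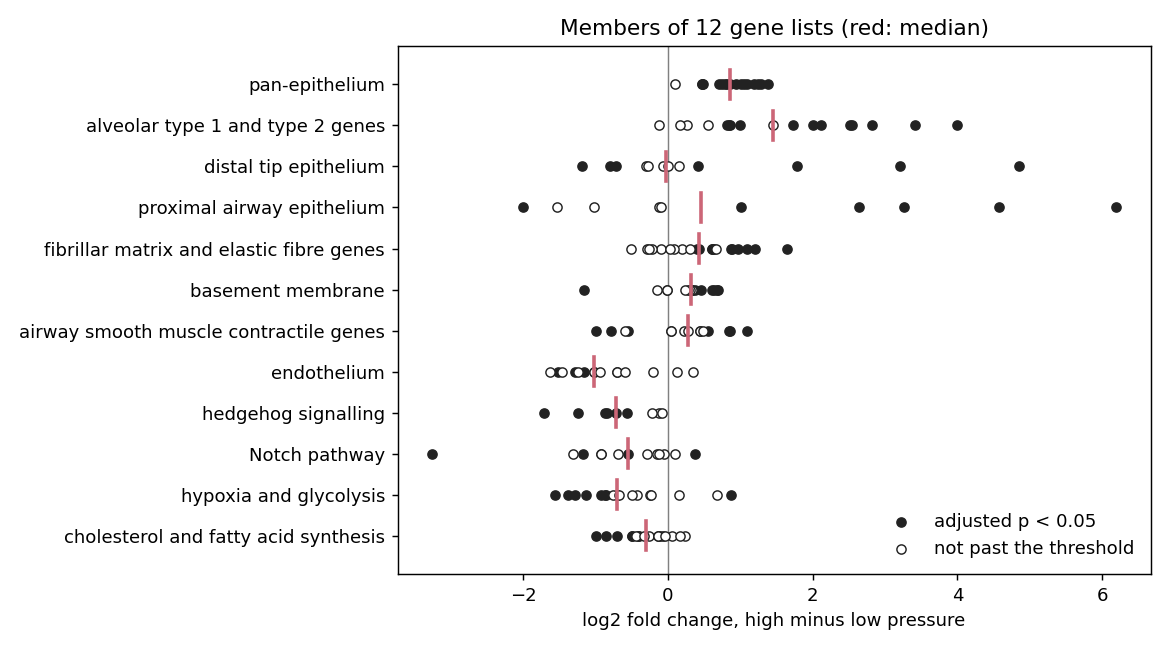
Log2 fold changes, high minus low pressure, of the members of 12 gene lists. Filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. All 16 called pan-epithelial genes lie above 0, and all 6 called hedgehog genes lie below it.

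In all, 3905 of 14937 genes tested differed between the pressures, 2089 higher and 1816 lower at high pressure, and 935 of them by a log2 fold change of at least 1 in size (543 higher, 392 lower). With offsets for GC content and length 2698 of 14751 genes differed, 1301 higher and 1397 lower, so the more frequent direction turned, also at a log2 fold change of at least 1 in size (341 higher, 397 lower). The median log2 fold change of all genes went from 0.0138 to -0.0435, and the offsets also evened out the library means. How much of the turn came from that was not tested. Of 37 lists tested 13 passed, 8 higher and 5 lower, 0 of them with an estimated correlation, and another division of the 6 libraries gave 12 passing lists. The count of lists was 8 without low pressure replicate 1. With fry 13 lists passed too. In the fit with a replicate block 1 list passed with fry and 11 with camera. The count of genes was 6257 without low pressure replicate 3, the library with fewer detected genes, and 2411, 1894 and 2016 without high pressure replicates 1, 2 and 3. It was 1121 with all 15 libraries in a single fit, which had no term for replicate 1 of the time series. It was 2212 after the component that separates replicate 1 of the time series was removed from each library. That removal ended the calls of the fibrillar matrix (median log2 fold change 0.43 before and 0.31 after, adjusted p = 0.102), basement membrane (0.32 and 0.25, 0.0552), mitosis (0.24 and 0.15, 0.116) and cell cycle inhibitor lists (0.16 over 14 and 0.44 over 12 members, 0.0739). The calls of the first 3 ended with smaller medians. In the inhibitor list 3 members rose after the removal, or 8 with 1 fallen adjusted over the list alone, against 5 both ways of adjusting before it, and the median was higher, so why its call ended stays open. Medians and counts came from edgeR before the removal and from limma-trend after it. The mesothelium list (median 0.36 before and 0.69 after) and the pericyte list (-0.36 and -0.53) passed after the removal (adjusted p = 0.00494 and 0.0189, and adjusted p = 0.672 and 0.712 with an estimated correlation). With the GC and length offsets 16 lists passed, 8 higher and 8 lower, 0 of them with an estimated correlation: the same 13 and, as lower, the pericyte, erythroid and retinoic acid lists. The scores on the removed component were -0.205 to -0.163 at low and 0.168 to 0.226 at high pressure, so its removal also takes away any effect of pressure along it.

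The second set of comparisons asked how gene expression changes in lungs developing in the embryo. By E14.5 lists of matrix, endothelial and alveolar genes were higher than at E12.5, and those of early embryonic timing and red cell genes were lower, with or without the replicate block, though each had adjusted p = 0.473 with an estimated correlation in the blocked fit. Single genes passed once replicate numbers were entered as a block. Col1a1, a fibrillar collagen (chromosome 11, 94936224 to 94953042, plus strand), averaged 509 ± 156 CPM at E12.5, 614 ± 189 at E13.5 and 942 ± 218 at E14.5 (SD, n = 3), and rose from E12.5 to E14.5 by a log2 fold change of 0.91 (SE 0.09, adjusted p = 0.00048) with the block. Hmga2 went from 1612 ± 1197 to 482 ± 270 CPM (SD, n = 3), a log2 fold change of -1.60 (SE 0.23), with the libraries of the stages overlapping and each numbered pair lower at E14.5. Scgb3a2 rose from 1.79 ± 1.48 to 31.3 ± 13.2 CPM (4.09, SE 0.77), and Acta2, the smooth muscle actin, from 241 ± 54.8 to 477 ± 133 CPM (0.96, SE 0.17). Ctgf rose too (0.66). The fold changes of Sox9 (-0.41), Fgf10 (0.36), Sftpc (1.41) and Shh (0.19) did not pass.

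The 10 largest rises from E12.5 to E14.5 with the block, among genes with a mean of at least 5 CPM and no overlap between the stages, were those of genes known from striated muscle. Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002079, plus strand), had 2 counts in the 3 E12.5 libraries together and 3947 at E14.5, where it averaged 68.4 ± 51.4 CPM (SD, n = 3), a ratio of 2155 with a counting interval of 596 to 17804. Ankrd1 rose by 7.53 on the log2 scale, and Alpk2 (6.73), Hspb7 (5.77), Fsd2 (5.77), Trim55 (5.72), Tnnc1 (5.22), Ldb3 (5.12), Actn2 (5.03) and Myo18b (4.95) followed. The largest falls under the same rule included 3 genes of the red cell membrane, Ermap (-3.15, SE 0.40), Kel (-2.59) and the anion exchanger Slc4a1 (-2.24). Others among them were Mcoln3 (-1.77), Astn1 (-1.77), the retinoic acid binding protein Crabp2 (-1.55), Slc4a8 (-1.54), Igdcc3 (-1.43) and Hsd11b2, which went from 18.9 ± 2.87 to 7.29 ± 4.23 CPM.

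Between E12.5 and E14.5, 18 lists passed without the block (13 higher, 5 lower) and 15 with it (11 higher, 4 lower), 0 of them with an estimated correlation, and the values below come from the blocked fit. Of 21 fibrillar matrix genes 10 rose and 0 fell, among them Postn (1.76), with 18 risen adjusted over the list alone (adjusted p = 5.64e-10, and adjusted p = 0.473 with an estimated correlation). Of 15 endothelial genes 8 rose and 0 fell, such as Emcn (0.77), Pecam1 (0.75) and Cdh5 (0.64), with 13 risen adjusted over the list alone (adjusted p = 2.90e-07, and adjusted p = 0.473 with an estimated correlation). Of 14 alveolar genes 6 rose and 0 fell, among them Hopx (2.65), Lyz2 (1.36) and Emp2 (1.15), with 9 risen adjusted over the list alone (adjusted p = 4.97e-05, and adjusted p = 0.473 with an estimated correlation). Lyz2 also belongs to the list of macrophages and other leukocytes, and which cells supplied the rise was not tested. In the skeletal and cardiac muscle list 9 of 14 members rose and 0 fell, with Myh3 (4.75) and Actn2 (5.03) as examples, and 13 rose and 1 fell adjusted over the list alone (adjusted p = 5.27e-10, and adjusted p = 0.473 with an estimated correlation). Of 12 genes of early embryonic timing 8 fell and 0 rose, also adjusted over the list alone, such as Igf2bp1 (-0.87) and Igf2bp2 (-0.48), with adjusted p = 7.19e-05, and adjusted p = 0.473 with an estimated correlation. Of 7 erythroid genes 2 fell, Slc4a1 and the red cell transcription factor Klf1 (-2.09), or 6 adjusted over the list alone (adjusted p = 9.09e-05, and adjusted p = 0.473 with an estimated correlation).

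**Figure D3:**
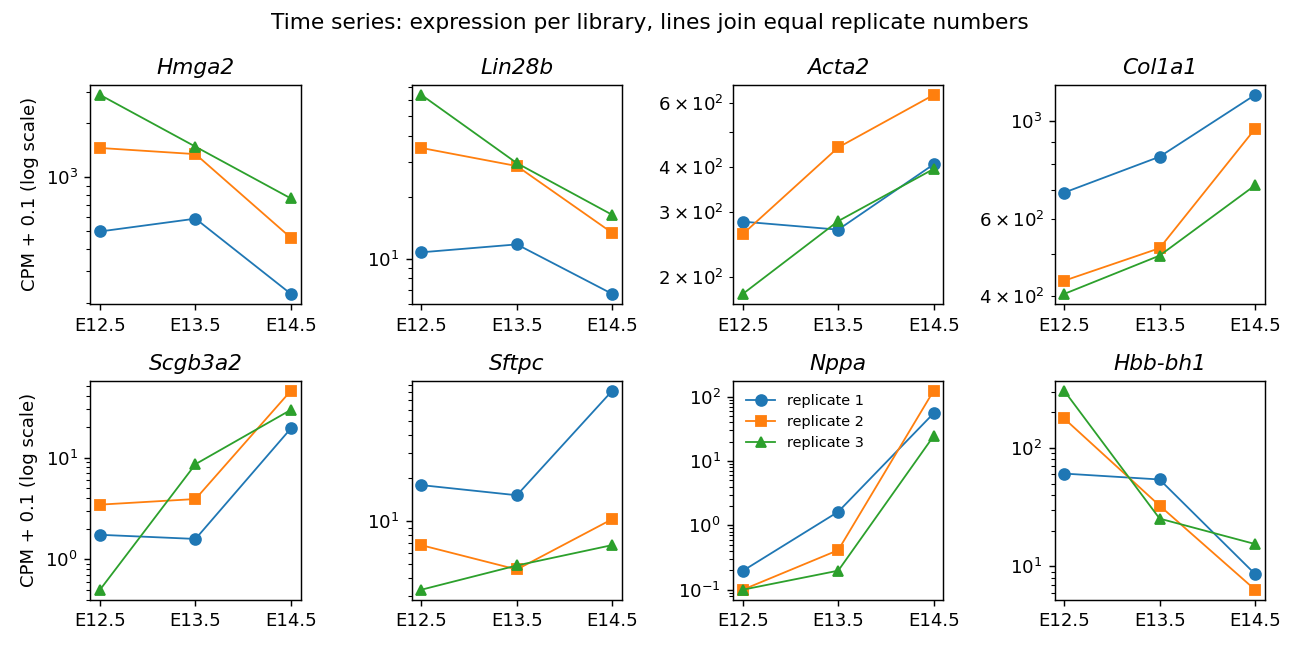
Expression of 8 genes in the time series, in CPM plus 0.1 on a log scale, with lines joining libraries of equal replicate number. Hmga2 was lower at E14.5 than at E12.5 within each replicate number, and Sftpc at E14.5 stood at 81.9 CPM in replicate 1 against 10.2 and 6.69 CPM in replicates 2 and 3.

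Without the block, as planned, edgeR called 0 of 14242 genes between E12.5 and E14.5, with 1328 at an unadjusted p under 0.05, while DESeq2 called 491 and limma-voom 0, and edgeR called 9 with no filter and 3 without E14.5 replicate 2. With the block 1561 genes differed, 1044 higher and 517 lower at E14.5. The blocked split was 928 higher and 728 lower with DESeq2 size factors and 1094 higher and 1850 lower, 2944 in all, with offsets for GC content and length. The median log2 fold change of all genes was -0.0340 and -0.0772 in these fits, against -0.00336, so the scaling of the libraries shifted too. The blocked count was 435, 869, 954, 755 and 636 without E12.5 replicates 2 and 3 and E14.5 replicates 1, 2 and 3. Replicate 1, whose ribosomal protein share was higher at every stage, differed from replicates 2 and 3 in 9405 genes across the series.

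More genes passed from E13.5 to E14.5 than from E12.5 to E13.5. From E13.5 to E14.5 Nppa rose by 6.64 on the log2 scale (SE 0.60, adjusted p = 0.00919) with the block, and Fsd2 (4.25), Ankrd1 (4.17) and Xirp1 (4.05) rose. Astn1 (-1.62), the urea transporter Slc14a1 (-1.54) and Crabp2 (-1.32) fell. Col1a1 rose by 0.64 and Ctgf by 0.86, and Fgf9, a signal from epithelium and mesothelium, fell by 0.43 on the log2 scale. Of 15 endothelial genes 9 rose and 0 fell, with 14 risen adjusted over the list alone (adjusted p = 1.12e-08, and adjusted p = 0.462 with an estimated correlation). Without the block edgeR called 0 genes, with 977 at an unadjusted p under 0.05, while DESeq2 called 293 and limma-voom 0. With the block 856 differed, 591 higher and 265 lower at E14.5. The blocked split was 500 higher and 381 lower with DESeq2 size factors and 637 higher and 944 lower, 1581 in all, with offsets for GC content and length. Here the median log2 fold change of all genes was -0.0352 and -0.0707, against -0.00200. The blocked count was 1296 without E12.5 replicate 3, 187 and 77 without E13.5 replicates 1 and 2, and 400, 402 and 328 without E14.5 replicates 1, 2 and 3.

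From E12.5 to E13.5 few genes passed. None of the 14 markers did, with blocked log2 fold changes of 0.45 for Acta2, 0.31 for Fgf10 and -0.08 for Sox9. Ifi204, an interferon-inducible gene with close paralogs, was lower at E13.5 in the blocked fit, with 1 count in the 3 E13.5 libraries and 200 at E12.5, a ratio of 0.00531 with a counting interval of 0.000134 to 0.0299. The erythroid list was lower as a whole with the block (adjusted p = 1.18e-09, and adjusted p = 0.972 with an estimated correlation), although 0 of its 7 members passed and 3 fell adjusted over the list alone. The airway smooth muscle list was higher (adjusted p = 0.000172, and adjusted p = 0.972 with an estimated correlation), with 0 of 15 members past the threshold, also adjusted over the list alone. Without the block edgeR called 0 genes, with 123 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With the block DESeq2 called 10 and limma-voom 0, while edgeR called 1, with 553 at an unadjusted p under 0.05. The blocked edgeR count was 41 without E12.5 replicate 1, 2 without E12.5 replicate 2 or E13.5 replicate 2, 3 and 4 without E14.5 replicates 1 and 2, and 0 without E12.5 or E13.5 replicate 3.

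The difference between the daily steps was tested directly. Without the block edgeR called 0 genes, with 233 at an unadjusted p under 0.05, while DESeq2 called 4 and limma-voom 0. With the block the signed difference between the steps passed for 3 genes, whose fitted log2 fold changes were negative in the first step and positive in the second: Ildr2 (-0.71 and 1.88), Strip2 (-1.64 and 4.24) and Ifi204, which had 1 count at E13.5. The blocked count was 7, 1 and 31 without E12.5 replicates 1, 2 and 3, 1, 0 and 11 without E13.5 replicates 1, 2 and 3, and 8 without E14.5 replicate 2, and it was 50 with DESeq2 and 0 with limma-voom.

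The last comparison asked whether lungs at high pressure lay further along the course of development than lungs at low pressure. Genes risen between E12.5 and E14.5 leaned higher at high pressure, and fallen genes leaned lower. Both comparisons set pools of 3 lungs against pools of 6, so an effect of pool size would act the same way in both. It cannot be told apart from a shared course in the sets, the score, the shared calls or the correlation. Of 302 risen genes tested in the cultured lungs, 77 were higher at high pressure, 14 lower and the rest not past the threshold, with a median log2 fold change of 0.40 (adjusted p = 8.28e-05, and adjusted p = 0.0469 with an estimated correlation). Of 76 fallen genes 20 were lower and 2 higher, with a median of -0.56 (adjusted p = 1.47e-05, and adjusted p = 0.0678 with an estimated correlation). Some lists went the other way: the endothelial list was lower at high pressure (adjusted p = 0.00948) and higher at E14.5 (adjusted p = 2.90e-07), and the Notch list likewise (adjusted p = 0.0233 and 0.00678). With an estimated correlation the endothelial list had adjusted p = 0.781 for pressure and 0.473 for stage, and the Notch list adjusted p = 0.680 and 0.473. The developmental score averaged -1.65 ± 1.01 at E12.5, -0.66 ± 0.27 at E13.5 and 2.15 ± 0.61 at E14.5, and it was -0.25 ± 0.18 at low and 0.83 ± 0.14 at high pressure (SD, n = 3). The difference of 1.07 had p = 0.1 in an exact two-sided permutation test, the smallest p that 3 libraries against 3 allow. The tables were scaled separately. The score rested on 340 risen and 94 fallen genes in the time series and on 302 and 76 of them in the cultured lungs. The sets were chosen from the E12.5 and E14.5 libraries, so the gap between those stages follows from the choice. Levels across the tables are therefore set side by side and not tested, and they do not place a pressure group at a stage. With all genes past the threshold in the sets, whatever their fold change (1044 risen and 517 fallen), the difference between the pressures was 0.575.

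**Figure D4:**
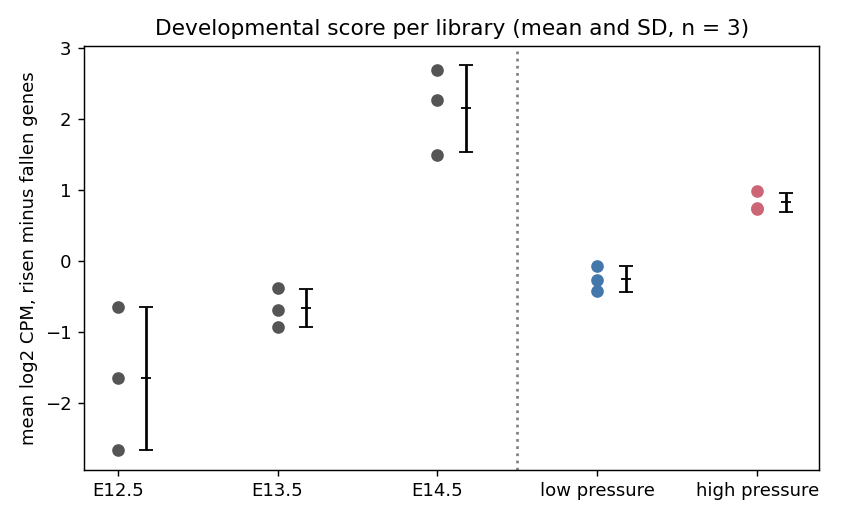
Developmental score of each library, the mean log2 CPM of genes risen from E12.5 to E14.5 minus that of genes fallen, with mean and SD of 3 libraries beside the points. The score averaged -0.25 at low and 0.83 at high pressure, and -0.66 at E13.5 and 2.15 at E14.5. The genes were chosen from the time series and fewer of them were tested in the cultured lungs, so the data sets do not share a scale.

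Genes called in both data sets mostly moved the same way, in comparisons that share the difference in pool size. With the block in the time series, 458 genes changed in the same direction in both, where independent lists would share 209, and 116 in opposite directions, where they would share 200. Both higher were Scgb3a2, the mesothelial marker Msln (3.91 with pressure and 3.69 with stage), Tmod1, Mrgprf, Cym and the carbonyl reductase Cbr2. Among those lower in both were Hmga2, Lin28b and the transcription factors Sp8 (-2.73 and -3.10), Alx1 and Lhx3. Hdac9 (-2.08 and 1.34), Trp63, Dpp10, Egr2, Ccbp2 and Gabrb2 were lower with pressure and higher with stage, although Dpp10 had 3 counts at E12.5. Alpl (1.32 and -1.06), Cacnb3, Alad, Erdr1 and the histocompatibility genes H2-T24 and H2-Q4, which belong to a family of close copies, went the other way. The count of genes with the same direction was 175 without E14.5 replicate 3, 184 without E12.5 replicate 2, 247 and 248 without E14.5 replicates 1 and 2, 260 without E12.5 replicate 3, and 283 and 289 without high pressure replicates 2 and 3. The count with opposite directions was 77, 76 and 188 without low pressure replicates 1, 2 and 3, 53 and 66 without high pressure replicates 2 and 3, 229, 21 and 63 without E12.5 replicates 1, 2 and 3, and 72, 43 and 49 without E14.5 replicates 1, 2 and 3.

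Across 14017 genes, which are not independent replicates, the log2 fold changes of pressure and of E14.5 against E12.5 had a Spearman correlation of 0.198 and a Pearson correlation of 0.207. Exact reassignment of the pressure labels gave p = 0.3 for the Spearman and p = 0.1 for the Pearson correlation, where 0.1 is the smallest possible. With the block the correlations were 0.177 and 0.200, with the same exact p-values. The Spearman correlation without the block was -0.0426 without E12.5 replicate 3 and -0.146 without E14.5 replicate 1, 0.443 and 0.0798 without E12.5 replicates 1 and 2, and 0.372 and 0.369 without E14.5 replicates 2 and 3. With the block it was 0.112 without E12.5 replicate 1. The first day of development, E13.5 against E12.5, also with pools of 3 against 6 lungs, gave -0.0194 without and -0.0490 with the block. The second day, E14.5 against E13.5, with 3 lungs per pool at both stages, gave 0.247 without and 0.245 with the block.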

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

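The alternative settings of the step test with the replicate block were chosen only after its result was seen, while the step test, the block and the count of other groupings were planned. In that test 3 genes changed by different amounts from E12.5 to E13.5 and from E13.5 to E14.5, as tested by the difference itself. They were named after their values were seen. For Ifi204 the second step minus the first was 13.80 on the log2 scale (SE 1.42, adjusted p = 0.00908). That fitted value and the SE derived from it depend on the prior count, because the gene had 200 counts at E12.5, 1 at E13.5 and 129 at E14.5. Counted directly, E12.5 stood 188 times above E13.5 (counting interval 33.4 to 7477) and E14.5 133 times above it (23.4 to 5281). The swing lay in replicates 2 and 3, with 2.66 and 6.92 CPM at E12.5, 0 and 0.0489 at E13.5 and 3.78 and 2.97 at E14.5, whereas replicate 1 had 0.144 CPM or less at every stage. Ifi204 has close paralogs, and no explanation of its swing was tested.

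For Ildr2 the second step minus the first was 2.59 on the log2 scale (SE 0.34, adjusted p = 0.0439), with means of 7.64, 4.71 and 17.3 CPM at the 3 stages. For Strip2 this difference was 5.88 (SE 0.79, adjusted p = 0.0439), with means of 0.789, 0.254 and 5.23 CPM. Of 100 assignments of the stages within replicate numbers, 8 gave at least the real 3 genes, the real one included, and the highest other gave 2361. Assignments that put E14.5 or E12.5 in the place of E13.5 can turn the change between stages itself into a difference of steps. The share therefore cannot decide about chance, which is not excluded for this count. Why some assignments gave several times the real count was not tested. Without the block all 100 groupings drawn gave at least the real 0 genes, as any grouping must, and the highest other gave 5144. In the real grouping edgeR had 233 genes at an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0.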

How the results depend on the processing

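The batch term, replicates 2 and 3 alone, the GC and length offsets, the component removal, the thinning, leaving out the muscle list or a replicate number of every stage, and every alternative to a blocked fit of the time series or to the blocked correlation were chosen after seeing the data. The blocked developmental sets, score and overlap were chosen then too, and their other alternatives had been planned for the sets without the block. The count of genes changed with pressure, 3905, stayed within 1.5 times under DESeq2 size factors, library totals, no filter, a minimum of 1 CPM, DESeq2, limma-voom, thinning and GC and length offsets, although with the offsets (2698) more genes were lower than higher. It was 1121 with all 15 libraries in a single fit, 935 with an absolute log2 fold change of at least 1, 2212 with the replicate 1 component removed, and 1894 to 6257 when 1 library was left out. The single fit had no term for replicate 1, so the spread it used included the replicate 1 difference of the time series. With a replicate block, although same-numbered cultured libraries correlated at only -0.0124 to 0.0461, the count was 3137. Between E13.5 and E12.5 the count of 0 became 1 with the block and 1 with a batch term, and stayed 0 when 1 library was left out. Between E14.5 and E13.5 it became 856 with the block, 293 with DESeq2, 808 with the batch term and 62 with replicates 2 and 3 only. Between E14.5 and E12.5 it became 1561 with the block, 491 with DESeq2, 9 with no filter, 1592 with the batch term and 1119 with replicates 2 and 3 only, and it ranged from 0 to 3 (without E14.5 replicate 2) when 1 library was left out. The step difference gave 3 genes with the block, 4 with DESeq2, 2 with the batch term and 1 with replicates 2 and 3 only. The cause was not tested.

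With the block, the count between E13.5 and E12.5 was 0 without the block, 10 with DESeq2, 0 with limma-voom and 0 to 41 when libraries were left out. Between E14.5 and E13.5 it was 0 without the block, 1581 with GC and length offsets, 265 with the fold change minimum and 77 to 1296 when libraries were left out. Between E14.5 and E12.5 it was 0 without the block, 2944 with GC and length offsets, 434 with the fold change minimum and 314 (without replicate 2 of every stage) to 1977 when libraries were left out. The step difference was 0 without the block, 1 with DESeq2 size factors, 9 with no filter, 1 with a minimum of 1 CPM, 50 with DESeq2, 0 with limma-voom and 0 to 94 (without replicate 3 of every stage) when libraries were left out. A group left with fewer libraries was assumed to vary like the others. The cause was not tested.

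An estimated correlation left 0 lists in every comparison. The pressure lists, 13, ranged from 8 to 14 when 1 library was left out. Fry gave 13 pressure lists, 9 with the replicate 1 component removed, 11 with the offsets and 1 with the replicate block. The 5 lists between E13.5 and E12.5 became 0 with fry and 1 to 10 when 1 library was left out, or, with the block, 6 became 0 with fry and 2 to 8. The 20 and 18 lists of the other time comparisons became 3 and 3 with fry, and with the block 17 and 15 became 10 and 9, while leaving out 1 library gave 15 to 20 and 14 to 19 without the block and 15 to 19 and 15 to 18 with it. Bax (-0.28) and Tbx4 (-0.14) lay below 0 with the replicate 1 component removed, against 0.54 and 0.42. The cause was not tested.

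The sets of genes risen and fallen in development, planned without the block, were empty, as was the score, and the first day gave 0 risen genes and 1 fallen gene, too few for a value. The blocked sets kept their calls when 1 library, or 1 replicate number of the time series, was left out (adjusted p of 1.22e-06 to 0.00338 for risen and 1.83e-07 to 0.00436 for fallen genes), and the fallen set lost its call with an estimated correlation (adjusted p = 0.0678). The score difference of 1.07 was 0.575 with the adjusted p alone, 0.828 with the replicate 1 component removed and 0.762 to 1.21 when 1 library was left out. The correlation of 0.198 was -0.0194 with E13.5 against E12.5, 0.247 with E14.5 against E13.5, 0.259 with the component removed, 0.243 with GC and length offsets and -0.146 to 0.443 when 1 library was left out, with -0.0426 without E12.5 replicate 3. With the block, 0.177 became -0.0490, 0.245, 0.253 and 0.230 in that order, and 0.112 to 0.263. Genes called in both data sets without the block, 0, were 164 with DESeq2 and 0 when 1 library was left out. With it, 458 in the same direction ranged from 175 to 613, and 116 in opposite directions from 21 to 229, with 189 by DESeq2 and 70 with the component removed. The cause was not tested.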

Other observations

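The tests on the distal tip list and on ventricular and atrial genes, the removal of the replicate 1 component, the GC and length offsets and the thinning were chosen only after the data were seen. The bound of the ventricular test was written before its value was seen. Lists outside the comparisons above also held genes that differed between the pressures. In the mesothelium list 3 of 9 members were higher at high pressure, among them Msln (3.91) and Upk3b (0.51), 0 were lower, and the counts were the same adjusted over the list alone, while the list did not pass (adjusted p = 0.0674) before the component that separates replicate 1 of the time series was removed. In the pericyte list Cox4i2 (-1.04), Abcc9 (-1.20) and Pdgfrb (-0.38) fell, 3 of 8 members, also adjusted over the list alone, and the list did not pass (adjusted p = 0.0561) without that removal or offsets for GC content and length. After the removal both lists passed (adjusted p = 0.00494 for mesothelium and 0.0189 for pericytes), with adjusted p = 0.672 and 0.712 with an estimated correlation. With the offsets the pericyte list passed (adjusted p = 0.0258, and adjusted p = 0.607 with an estimated correlation) and the mesothelium list did not (adjusted p = 0.229). In the BMP and TGF-beta list 6 of 16 members rose and 0 fell, also adjusted over the list alone, with the latent TGF-beta binding protein Ltbp2 (2.08), Bmp5 (0.89) and Tgfb3 (0.70) as examples (adjusted p = 0.106). The chemokine gene Cxcl12 fell (-1.52) and the adhesion molecule gene Icam1 rose (1.40), in an inflammatory list with 4 of 14 members higher and 2 lower, also adjusted over the list alone (adjusted p = 0.604). In the retinoic acid list Aldh1a1 rose (2.08) and Cyp26b1, which degrades retinoic acid, fell (-1.56), with 2 of 15 members higher and 4 lower, or 3 and 4 adjusted over the list alone (adjusted p = 0.207). With the GC and length offsets this list was lower, with 2 members higher and 6 lower, or 2 and 8 adjusted over the list alone (adjusted p = 0.0323, and adjusted p = 0.664 with an estimated correlation). The erythroid list, which did not pass otherwise (adjusted p = 0.134), was lower with these offsets, with 3 of 6 members lower, also adjusted over the list alone (adjusted p = 0.0188, and adjusted p = 0.607 with an estimated correlation).

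Between E12.5 and E14.5, with the block, further lists passed. In the Notch list 5 of 13 members rose, such as Nrarp (0.72) and Heyl (0.51), and Notch3 fell (-0.32), with 6 and 1 adjusted over the list alone (adjusted p = 0.00678, and adjusted p = 0.473 with an estimated correlation). In the airway smooth muscle list 3 of 15 members rose, among them Tagln (0.49) and Tpm2 (0.55), or 6 adjusted over the list alone (adjusted p = 0.00139, and adjusted p = 0.490 with an estimated correlation). In the channel list 6 of 15 members rose, with Atp1b1 (1.72), Aqp1 (1.39) and Piezo2 (0.65) as examples, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 0.001, and adjusted p = 0.473 with an estimated correlation). Among S phase genes 1 of 20 fell, the cyclin gene Ccne1 (-0.40), also adjusted over the list alone (adjusted p = 0.000804, and adjusted p = 0.490 with an estimated correlation). Single libraries stood apart as well. E14.5 replicate 2 had 0.0525 CPM of the Y-linked Ddx3y and 3669 CPM of Xist, against 33.8 to 159 and 645 to 2205 CPM in the other libraries of the time series.

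Genes changed between high and low pressure were set against technical explanations. Thinning all 6 libraries to the shallowest kept 97.5% of the calls in the same direction (96.2% to 97.6% when 1 library was left out), which argues against sequencing depth. Offsets for GC content and transcript length kept 54.7% (36.6% to 66.1%), above the bound of 50% set beforehand but not by more than its spread, a requirement applied after the value was seen, and removing the component of replicate 1 of the time series kept 44.8% (24.5% to 54.1%), so both stay open for part of the calls. The component also separated the pressures, with scores of -0.205 to -0.163 at low and 0.168 to 0.226 at high pressure, so its removal takes away any pressure effect along it and the lost calls speak for neither. Pool size and any litter or culture run that moved with pressure cannot be told apart from it in this design, and pressure itself stays open. The 10 possible splits of 6 libraries are too few for a share under 0.05: 1 of them, the real one, gave 3905 genes and the highest other 0, and for lists 1 gave 13 and the highest other 12.

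The higher pan-epithelial and alveolar genes at high pressure had a median log2 fold change of 0.97. After the replicate 1 component was removed it was 0.758 over 31 members (0.665 to 0.897 when 1 library was left out), and with GC and length offsets it was 0.759 over 34 members (0.678 to 0.790), which argues against either as the whole cause. A larger share of epithelial cells alone would raise distal tip genes alike. Their median minus that of the pan-epithelial list was -0.887 on the log2 scale. In the 9 pairs of 1 high and 1 low library it was -1.01 to -0.634. The members went both ways, some past the threshold in each direction, with an SD of 1.81 (n = 12 genes), so the median itself decides nothing. A larger share alone does not account for the members that fell, provided that they mark epithelium only, which was not tested. For the risen genes a larger epithelial share stays open, and so does a changed state of the distal tips. The pools of 6 and 3 lungs were confounded with pressure here too.

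Heart muscle genes rose in the E14.5 libraries, with Myh6, which shares sequence with Myh7, at 329, 637 and 145 CPM in replicates 1 to 3. Ventricular tissue would bring Myl2 and Myl3, whose summed level was at most 2.56% of that of Myl7 and Myl4 in any E14.5 library, which argues against it. Atrial muscle or the heart-like muscle of the pulmonary veins stays open: 5 of 5 atrial genes (Nppa, Myl7, Myl4, Myh6 and Sln) were higher in all E14.5 libraries than in every E12.5 library, but 4 of them belong to the muscle list that showed the rise, so this value restates it and does not support the explanation. Real blocked counts were 1 gene for E13.5 against E12.5, 856 for E14.5 against E13.5 and 1561 for E14.5 against E12.5, each with 0 in the highest other of 4 splits that part the numbered pairs, of which 1 gave as many, and 4 splits are too few for a share under 0.05. Without the block the real counts and the highest others were 0 in edgeR for all 3 comparisons, so all 10 splits of each gave as many, with 123, 977 and 1328 genes at an unadjusted p under 0.05, 0, 293 and 491 by DESeq2 and 0 by limma-voom, and 10 splits are too few as well.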
